A study of Caenorhabditis elegans with 12 samples.

How the data were processed

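Early embryos of *Caenorhabditis elegans* were profiled for LEM-2 by chromatin immunoprecipitation followed by paired-end sequencing, with an input library beside each LEM-2 library. Per the labels' protocols, the strains were grown in parallel in independent biological replicates, chromatin was cross-linked with formaldehyde, and libraries were amplified by PCR without molecular identifiers. There were 3 genotypes (the wild type, the met-2 set-25 double mutant and the cec-4 mutant), with 2 LEM-2 and 2 input libraries each, 12 in all.

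The authors deposited a table of raw counts per 200 kb window, with 1 column per library and 504 windows tiled from the first base of each chromosome, the last window of each being shorter. Per the submitters' processing notes Bowtie was used, with no version given. The genome build, the read filters and the way a read pair was counted are not given in the sources used here. The authors also deposited log2 values for the same windows, and a check showed that each value was log2 of the count times the mean library total over the library total plus 1, with a largest difference of 5.15e-14 and 0 values outside a tolerance of 1e-09. These log2 values are a rescaling of the counts and served only as an alternative for the region values.

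Depth ranged from 10750212 to 12340446 counts per library and was similar between genotypes and between LEM-2 and input. The median window held between 19480 and 24830 counts. If each count was an independent fragment, Poisson counting error was at most 0.716% of such a count. The error was larger if both reads of a pair were counted or PCR copies were kept. The last window of I took between 0.492% and 1.18% of the counts of a library. Chi-square per degree of freedom between the 2 replicates of a group lay between 2.54 and 73.9, so no 2 replicates held the same counts. The lowest value, for the input of met-2 set-25, does not clearly exceed counting error if both reads of a pair were counted. Chi-square per degree of freedom was highest for LEM-2 in cec-4 (73.9), against 33.3 in wild-type and 19.4 in met-2 set-25.

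Windows were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on the raw counts, in one fit of all 12 libraries with a mean per group, with the library total as the only scaling and Benjamini-Hochberg adjustment over the 504 windows at a threshold of 0.05. Changes in LEM-2 enrichment were tested as the LEM-2 minus input contrast in one genotype minus that in another. A filter of at least 100 counts per window on average removed 0 windows, the smallest mean being 4515, so the alternative without a filter was void.

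Region values were the mean over a region's windows of log2 of LEM-2 over input, each in CPM plus 1, with the input of the same genotype and replicate number. They were tested with limma 3.58.1 over 23 region lists, namely the left arm, centre and right arm of the 6 chromosomes (18 regions), the autosomal arms, centres, outer and inner parts of the autosomal arms (each arm divided at its midpoint), and the first 4 Mb of X. The library and not the window was the replicate in these tests. Left arms ended and right arms began at 4 and 11 Mb on I, 5 and 12 Mb on II, 4 and 10 Mb on III, 4 and 13 Mb on IV, 6 and 17 Mb on V, and 6 and 12 Mb on X. Limma gave all regions the same standard error, 0.04, since it shrank the variances of the regions to a common value. With 2 libraries per group this is an assumption the data can hardly test. The pooled lists overlap the regions and all lists come from the same libraries, so their spreads are not independent. The limma p-values treat them as independent and may be too small. Arm minus centre was compared by an exact two-sided permutation test.

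Windows were named by a rule. For LEM-2 against input they were the 3 highest and 3 lowest called wild-type windows on the same side of 0 in both libraries. For each mutant against wild-type they were the 5 largest rises and 5 largest falls among called windows in which both mutant libraries lay on the same side of both wild-type libraries, and for the other comparisons the 3 largest by the same rule or, with none called, the 3 with the smallest p. Grouping, tests, regions, naming rule and most of the alternative settings were fixed before the data were examined. Fits without the last window of I, with crossed wild-type numbers, with each region's own variance and of the 6 inputs alone were chosen after seeing the data. So were the other scalings of the end windows and a DESeq2 fit without LEM-2 met-2 set-25 replicate 2.

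The labels state that strains were grown in parallel in replicates, and the replicate numbers were taken as pairing the libraries. The difference of replicate 2 from replicate 1 was correlated between groups, and of 15 pairs of groups 7 had a correlation over 0.1 and 4 one under -0.1, the lowest being -0.55 between LEM-2 in wild-type and in met-2 set-25. A fit with the replicate number as a block was therefore an alternative. So was a fit with a block within each genotype, which pairs a LEM-2 library only with the input of its genotype and number. The main fit of the windows used no pairing.

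The alternatives were TMM and DESeq2 size factors, the DESeq2 1.42.0 Wald test, a stricter filter, autosomes only, the replicate block, other pseudocounts (0.1 and 10 CPM), pooled inputs, other arm boundaries, medians over windows, centring, the authors' log2 values, and leaving out each library in turn. The window test was tested on simulated counts for met-2 set-25 against wild-type over 504 windows, where it called 50% of windows changed 1.1-fold, 98% of those changed 1.2-fold and 100% of those changed 1.4-fold or 1.6-fold, and 7 of 304 unchanged windows. The region test over 23 lists for the same comparison called 42% of lists shifted by 0.1 and 100% of those shifted by 0.3. These lists were simulated as independent and with a common SD, as the test assumes. The real lists overlap and differ in spread, so these shares do not measure how the region test performs on them.

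No gene was placed on the windows, because the build of the windows is not named and the gene table at hand, of assembly WBcel235, has other chromosome ends. The gene lists, the windows of the mutated genes and the 5 planned corrections for GC content were not analysed here. Intervals and errors from counts cover counting error only, since PCR copies are not independent molecules.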

Results

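LEM-2, a protein of the inner nuclear membrane, was profiled by chromatin immunoprecipitation and sequencing in early embryos of *Caenorhabditis elegans*, to ask how chromatin anchoring at the nuclear periphery differs between wild-type worms, met-2 set-25 double mutants and cec-4 mutants. MET-2 and SET-25 are methyltransferases of histone H3 lysine 9, and CEC-4 is a chromodomain protein of the nuclear periphery that binds this methylated lysine. Each genotype had 2 LEM-2 libraries and 2 input libraries from independent biological replicates, which made 12 libraries in 6 groups. Counts in 504 windows of 200 kb covered chromosomes I to V and X, and the libraries held between 10750212 and 12340446 counts. The median window of a library held at least 19480 counts. If each count was an independent fragment, counting error was at or below 0.716% of that count. On that condition replicates differed by more than counting error in every group (chi-square per degree of freedom of at least 2.54). How a read pair was counted is not given, and both readings depend on it. Enrichment is given as log2 of LEM-2 over input. Each library was scaled to its own counts, so a fall in some windows goes with a rise in others. Rises and falls below are therefore relative, and no absolute gain or loss of LEM-2 contact was measured. Positions are those of the authors' windows, whose genome build is not given in the sources used here.

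In wild-type embryos LEM-2 was enriched on the arms of the autosomes and depleted from their centres. The mean log2 ratio was 0.40 ± 0.04 (SD, n = 2) over the 215 arm windows and -0.43 ± 0.05 (SD, n = 2) over the 200 centre windows. The outer parts of the arms, next to the chromosome ends, stood at 0.52 ± 0.05 and the inner parts at 0.28 ± 0.03 (SD, n = 2). Of the arm windows 183 were enriched and 17 depleted, and of the centre windows 11 were enriched and 177 depleted. The right arms of V and IV had the highest means of the 18 chromosome regions, at 0.61 ± 0.02 and 0.60 ± 0.03 (SD, n = 2), and the centre of III had the lowest, at -0.61 ± 0.05 (SD, n = 2). On X 70 of 89 windows were depleted and 10 enriched, and 8 of the 10 lay in the first 4 Mb.

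The most enriched wild-type windows were III 1.2 to 1.4 Mb (0.98), I 1.2 to 1.4 Mb (0.96) and the left tip of X, 0 to 0.2 Mb (0.94). The same windows stood at 0.56, 0.43 and 0.53 in met-2 set-25 and at 0.35, 0.40 and 0.21 in cec-4. The most depleted windows were III 5.8 to 6 Mb (-0.89), II 11.6 to 11.8 Mb (-0.87) and II 6.8 to 7 Mb (-0.84), which stood at -0.70, -0.68 and -0.69 in met-2 set-25 and at -0.75, -0.70 and -0.77 in cec-4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 468 of 504 windows differed from input in wild-type, 204 higher and 264 lower. The splits were 225 and 235 under TMM factors, 233 and 223 under DESeq2 size factors and 237 and 227 in the DESeq2 Wald test. Under library totals the median window lay at -0.12, and relative to it the median arm window lay at 0.57 and the median centre window at -0.36.

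**Figure D1:**
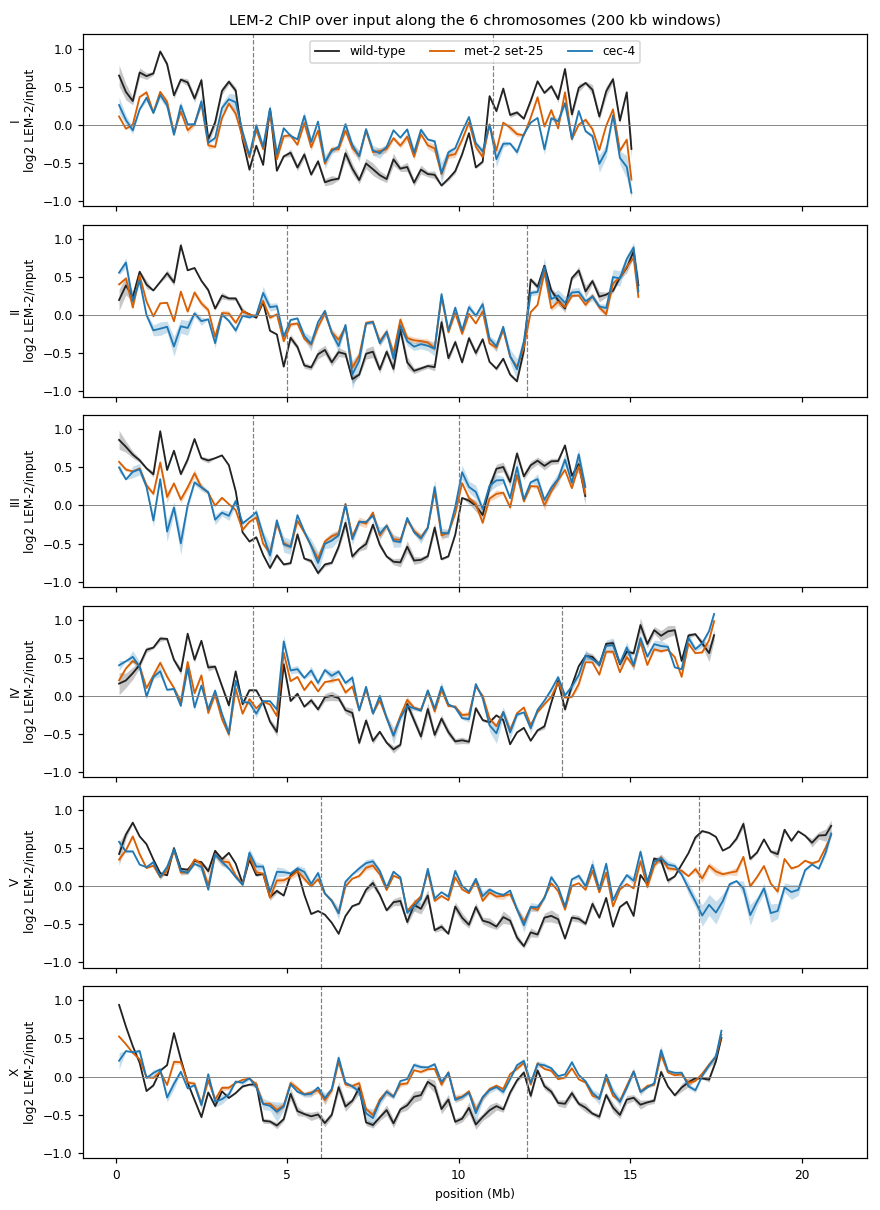
Log2 ratio of LEM-2 ChIP over input (y axis) in 200 kb windows against position in Mb (x axis) on the 6 chromosomes, with lines for the mean of the 2 replicates of each genotype, shading for their range and dashed lines for the arm boundaries. Wild-type windows lie above 0 on most of the autosomal arms (mean 0.40) and below 0 in the centres (mean -0.43), and both mutants lie closer to 0 (0.18 and -0.16 in met-2 set-25, 0.15 and -0.13 in cec-4).

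In both mutants fewer windows differed from input, 389 in met-2 set-25 (189 higher, 200 lower) and 411 in cec-4 (196 higher, 215 lower). Of the 204 windows enriched in wild-type, 151 were also enriched in met-2 set-25 and 11 were depleted there, and in cec-4 these numbers were 134 and 39. On the left arm of V 22 of 23 windows enriched in wild-type were also enriched in either mutant. On the right arm of IV these were 21 of 22 in met-2 set-25 and 22 of 22 in cec-4, and on the right arm of II 13 of 16 and 16 of 16. On the right arm of I 5 of 18 stayed enriched in either mutant, and 5 became depleted in met-2 set-25 and 11 in cec-4. All 20 windows of the right arm of V were enriched in wild-type, of which 16 were enriched in met-2 set-25 and 5 in cec-4.

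In met-2 set-25 embryos LEM-2 enrichment, relative to the library total, fell on the arms of the autosomes and rose in their centres. The arms fell by 0.22 and the centres rose by 0.27 on the log2 scale (SE 0.04, n = 2 against 2, limma adjusted p = 1.43e-06 and 2.86e-08). The right arm of I fell by 0.38, the right arm of V fell by 0.37, the left arm of I fell by 0.34, the left arm of III fell by 0.31 and the left arm of IV fell by 0.28. Smaller falls were seen on the right arm of III (-0.20), the left arm of II (-0.16), the right arm of II (-0.14) and the right arm of IV (-0.13). Every autosomal centre rose, from 0.23 on IV to 0.30 on II. The left arm of V did not pass the test (-0.01, limma adjusted p = 0.797).

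Single windows followed the same division. Of the 215 arm windows 142 fell and 13 rose, and of the 200 centre windows 171 rose and 4 fell. The largest falls were at I 2 to 2.2 Mb (-0.63), III 2.8 to 3 Mb (-0.62), I 14.8 to 15 Mb (-0.62), V 17 to 17.2 Mb (-0.62) and II 1.8 to 2 Mb (-0.61). The largest rises were at III 9.2 to 9.4 Mb (0.48), II 6 to 6.2 Mb (0.47), V 13.4 to 13.6 Mb (0.47), I 8.8 to 9 Mb (0.46) and IV 9.8 to 10 Mb (0.46). By edgeR 399 of 504 windows changed, 249 higher and 150 lower. The split depended on the scaling between libraries, with 189 higher and 183 lower under TMM factors, 153 and 195 under DESeq2 size factors and 167 and 202 in the DESeq2 Wald test. Under library totals the median window shifted by 0.15, and relative to that shift the median arm window changed by -0.40 and the median centre window by 0.14.

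The calls on 3 arms in met-2 set-25 rested on the pooled spread or on 1 library. With each region's own variance in place of limma's moderated one, the adjusted p was 0.125 for the right arm of II, 0.0629 for the right arm of III and 0.0603 for the right arm of IV. Without wild-type replicate 1 the right arm of II had -0.09 (adjusted p = 0.113 in limma), and without met-2 set-25 replicate 1 the right arm of IV had -0.11 (adjusted p = 0.0534 in limma). Under TMM factors the autosomal arms fell by 0.32 and the centres rose by 0.17, and the left arm of V then also fell (-0.11, limma adjusted p = 0.0148).

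In cec-4 embryos the same division was seen, with a relative fall of the autosomal arms and a relative rise of the centres. The arms fell by 0.25 and the centres rose by 0.29 (SE 0.04, n = 2 against 2, limma adjusted p = 5.46e-08 and 2e-09). The right arm of V fell by 0.64, the right arm of I fell by 0.52, the left arm of III fell by 0.45, the left arm of I fell by 0.31, the left arm of IV fell by 0.29 and the left arm of II fell by 0.25. The autosomal centres rose by 0.26 on IV to 0.32 on I. The right arms of II (-0.06) and IV (-0.05) and the left arm of V (0.01) did not pass the test, with limma adjusted p of 0.146, 0.218 and 0.887. Without cec-4 replicate 2 the right arm of II passed it (-0.12, limma adjusted p = 0.017). It also did so with medians over windows (-0.12, 0.0145), with the mean of all 6 inputs (-0.093, 0.0319) and with the replicate block and crossed wild-type numbers (0.0383).

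Of the 215 arm windows 127 fell and 24 rose in cec-4, and of the 200 centre windows 168 rose and 6 fell. The largest falls were at V 17 to 17.2 Mb (-1.10), II 1.8 to 2 Mb (-1.06), V 17.4 to 17.6 Mb (-0.98), I 14.8 to 15 Mb (-0.97) and V 17.2 to 17.4 Mb (-0.94). The largest rises were at V 13.4 to 13.6 Mb (0.56), III 9.2 to 9.4 Mb (0.53), I 5.8 to 6 Mb (0.52), I 8.8 to 9 Mb (0.52) and V 13.8 to 14 Mb (0.51). By edgeR 394 of 504 windows changed, 255 higher and 139 lower, with splits of 184 and 183 under TMM factors, 182 and 184 under DESeq2 size factors and 197 and 193 in the DESeq2 Wald test. Under library totals the median window shifted by 0.16, and relative to it the median arm window changed by -0.38 and the median centre window by 0.16.

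The right arm of III in cec-4 (-0.09, limma adjusted p = 0.0355) was a weak call under library totals. Its limma adjusted p was 0.0657 with the replicate block, 0.157 after centring on the median autosomal window and 0.306 with its own variance. Its value was -0.039 without wild-type replicate 1 and -0.037 without cec-4 replicate 1, and the call was lost in both fits. Leaving out either met-2 set-25 replicate also ended the call, while the value stayed at -0.09. Those libraries do not enter this difference, and only the shared spread behind the test changed. Under TMM factors, in contrast, the right arm of III had a larger fall (-0.22, limma adjusted p = 5.52e-06). The autosomal arms then fell by 0.38 and the centres rose by 0.17. The right arms of II (-0.19) and IV (-0.18) and the left arm of V (-0.12) then also fell, so the sign of the left arm of V depended on the scaling.

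On X the centre rose by 0.25 in met-2 set-25 and by 0.26 in cec-4, and the right arm by 0.20 and 0.21 (SE 0.04, n = 2 against 2 in limma). By edgeR 65 of 89 windows of X rose and 4 fell in met-2 set-25, and 63 rose and 6 fell in cec-4. The left arm of X had 0.07 and 0.03 and its first 4 Mb had 0.00 and -0.05, none of which passed the test. The left arm in met-2 set-25 passed it as a rise with medians over windows (0.11, limma adjusted p = 0.0228) and with the replicate block and crossed wild-type numbers (0.00732). The first 4 Mb in cec-4 passed it as a fall with that block (0.0318) and with its own variance (0.0486). Under TMM factors the left arm of X had -0.02 in met-2 set-25 and -0.09 in cec-4 (limma adjusted p = 0.605 and 0.0324), and the first 4 Mb had -0.09 and -0.18 (adjusted p = 0.0293 and 1.11e-04). The direction of the left arm of X in both mutants and of the first 4 Mb in met-2 set-25 thus turned with the scaling, while the first 4 Mb in cec-4 lay below 0 under both. The rises of the centre and the right arm of X kept their sign under TMM factors, at 0.16 and 0.10 in met-2 set-25 and at 0.13 and 0.09 in cec-4. These rises too are relative to the other windows of a library.

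**Figure D2:**
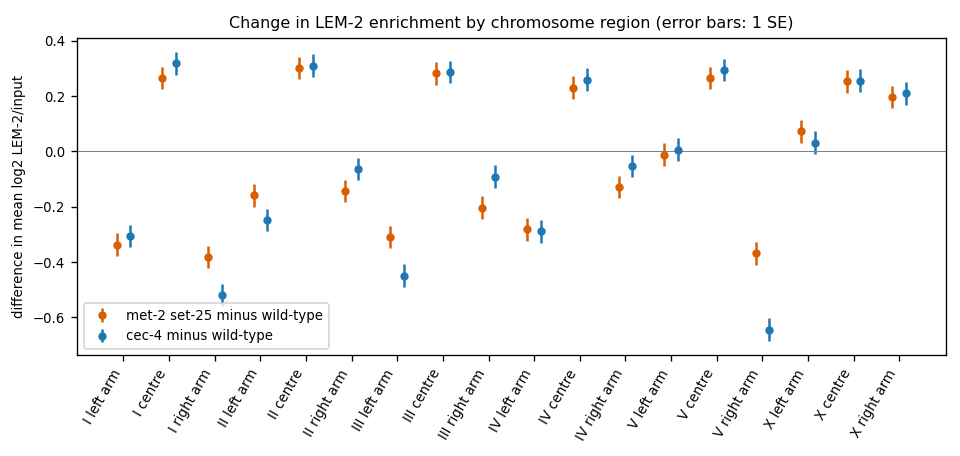
Difference from wild-type in mean log2 LEM-2 over input (y axis) for the 18 chromosome regions (x axis), with points for each mutant and bars for 1 standard error (0.04, limma). The centres lie above 0 (0.23 to 0.32) and most autosomal arms below it under library-total scaling, the lowest being the right arm of V in cec-4 (-0.64), while the left arm of V lies at -0.01 in met-2 set-25 and 0.01 in cec-4 (-0.11 and -0.12 under TMM factors, which are not drawn).

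The height of the autosomal arms above the centres, a value that needs no scaling between libraries, was 0.83 ± 0.08 in wild-type, 0.34 ± 0.05 in met-2 set-25 and 0.28 ± 0.03 in cec-4 (SD, n = 2). It fell by 0.49 to 41.2% of the wild-type value in met-2 set-25 and fell by 0.55 to 34.0% in cec-4. The wild-type libraries had 0.89 and 0.77, the met-2 set-25 libraries 0.30 and 0.38 and the cec-4 libraries 0.26 and 0.30, so each difference from wild-type was larger than the spread between replicates. The two-sided exact permutation test gave p = 0.333 for each mutant, which is the smallest value that 2 against 2 libraries can give.

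**Figure D3:**
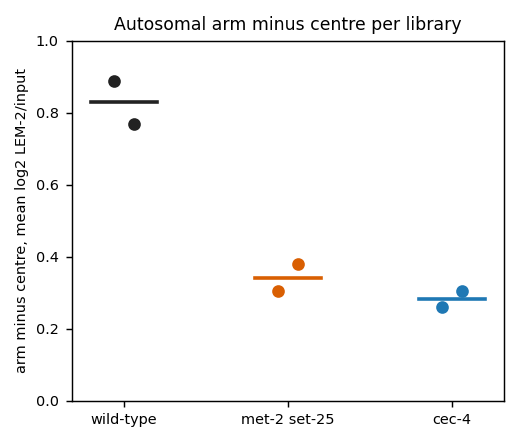
Autosomal arm minus centre, as mean log2 LEM-2 over input (y axis), for each library of the 3 genotypes (x axis), with points for libraries and bars for the mean. The wild-type libraries lie at 0.77 and 0.89, and the 4 mutant libraries between 0.26 and 0.38.

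The inputs measure the background without the antibody. By edgeR 0 of 504 windows differed between the inputs of met-2 set-25 and wild-type and 0 between those of cec-4 and wild-type, with 0 windows at an unadjusted p under 0.05 in each comparison and 0 called by DESeq2. Chance alone would give 25.2 windows at that unadjusted p, so these 0 calls, in a fit whose spread was shared with the more variable LEM-2 libraries, are no evidence that the inputs were equal. In a fit of the 6 inputs alone edgeR also called 0, but 18 windows in met-2 set-25 and 86 in cec-4 lay at an unadjusted p under 0.05, and DESeq2 called 1 and 20. In the fit of all libraries the windows with the smallest p were V 18.6 to 18.8 Mb (0.07), V 20 to 20.2 Mb (0.05) and I 11.4 to 11.6 Mb (-0.04) in met-2 set-25, and I 11.4 to 11.6 Mb (-0.08), I 0.8 to 1 Mb (-0.08) and X from 17.6 Mb to the right end (-0.09) in cec-4. Arm minus centre of the inputs was -0.15 and -0.14 in wild-type, -0.14 and -0.13 in met-2 set-25 and -0.18 and -0.18 in cec-4, so both cec-4 inputs lay below the other 4.

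The changes of both mutants went together across windows, with Pearson's r of 0.95 and Spearman's rho of 0.97 over the 504 windows, which are not independent replicates. Autosomal arms fell and centres rose in both mutants, so r over all windows includes this shared division. By itself r does not show agreement of windows within arms or within centres. Both comparisons used the same wild-type libraries, and simulated unchanged mutants against them gave r of 0.50 ± 0.03 and rho of 0.48 ± 0.04 (SD, 100 simulations). The covariance was 0.100 against 0.00204 in the simulations, a difference of 0.098, and 94.6% of windows changed in the same direction against 66.4%. Of the windows that rose, 238 were shared between the 249 of met-2 set-25 and the 255 of cec-4, where independent lists would share 126, and of those that fell, 133 were shared between 150 and 139, where 41.4 would be. Simulated unchanged mutants shared 0 called windows in each of the 100 simulations, in which at most 3 were called. The simulated windows varied independently, while the wild-type replicates differed over whole arms and centres (arm minus centre 0.89 and 0.77). The simulations may therefore understate the spread of r and the sharing that unchanged libraries would give. The number for independent lists leaves out the shared controls, and part of the excess may come from them. With a different wild-type library for each mutant, so that no control was shared, r was 0.90 and 0.96.

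Between the mutants themselves the right arm of V differed most, with 0.24 ± 0.03 in met-2 set-25 and -0.03 ± 0.10 in cec-4 (SD, n = 2), a difference of 0.28 (SE 0.04, limma adjusted p = 9.67e-08). LEM-2 was also higher in met-2 set-25 than in cec-4 on the right arm of I (0.14) and the left arm of III (0.14), and lower on the right arm of III (-0.11). By edgeR 41 of 504 windows differed, 38 higher and 3 lower in met-2 set-25, of which 12 lay on the right arm of V and 7 each on the right arm of I, the left arm of II and the left arm of III. The largest differences were at III 1.8 to 2 Mb (0.57), V 17.4 to 17.6 Mb (0.53) and V 17.2 to 17.4 Mb (0.51), and the lower windows were II 12 to 12.2 Mb (-0.25), III 10.6 to 10.8 Mb (-0.18) and II 12.2 to 12.4 Mb (-0.17).

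This comparison rested on few libraries. Without LEM-2 met-2 set-25 replicate 2, 0 windows were called by edgeR (81 at an unadjusted p under 0.05) and 34 by DESeq2, and without LEM-2 cec-4 replicate 1, 141 were called. Without input met-2 set-25 replicate 1, input cec-4 replicate 1 or input cec-4 replicate 2, 19, 23 and 26 windows were called, and the DESeq2 Wald test called 64 (49 higher, 15 lower). The right arm of V was the only 1 of the 4 regions that stayed past the limma threshold without each library pair in turn (0.20 to 0.35), and with each region's own variance none of the 4 did (4 of the 23 lists at an unadjusted p under 0.05), with an adjusted p of 0.238 for the right arm of V. With the replicate block the right arm of III lost its call (limma adjusted p = 0.109), as it did under TMM factors (0.185), with the mean of all 6 inputs (0.114) and with medians (0.0771). After centring the right arm of I and the left arm of III lost theirs (0.052 each). The left arm of II gained a call under TMM factors (0.12, limma adjusted p = 0.0358), with the mean of all 6 inputs (0.0257) and with the other arm boundaries (0.00478). Without cec-4 replicate 1 the right arm of II gained one (-0.14, limma adjusted p = 0.0296).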

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

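All tests of explanations in this part were chosen only after the result was seen, while the comparison between the mutants itself was planned. What drew attention was that the change from wild-type differed between the mutants by a direct test. By edgeR 41 windows differed in LEM-2 enrichment between met-2 set-25 and cec-4, but 0 did without LEM-2 met-2 set-25 replicate 2 (81 at an unadjusted p under 0.05, and 34 called by DESeq2), and 141 did without LEM-2 cec-4 replicate 1. With input met-2 set-25 replicate 1, input cec-4 replicate 1 or input cec-4 replicate 2 left out, 19, 23 and 26 windows differed. The largest window differences, as met-2 set-25 minus cec-4, were 0.57 at III 1.8 to 2 Mb, 0.53 at V 17.4 to 17.6 Mb, 0.51 at V 17.2 to 17.4 Mb, -0.25 at II 12 to 12.2 Mb, -0.18 at III 10.6 to 10.8 Mb and -0.17 at II 12.2 to 12.4 Mb.

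Of the regions, the right arm of I differed by 0.14, the left arm of III by 0.14, the right arm of III by -0.11 and the right arm of V by 0.28 (SE 0.04, n = 2 against 2 in limma). The right arm of I, the left arm of III and the right arm of III lost their calls without met-2 set-25 replicate 1 (limma adjusted p = 0.0926, 0.076 and 0.505), without met-2 set-25 replicate 2 (0.206, 0.217 and 0.206) and without cec-4 replicate 2 (0.29, 0.214 and 0.787). Leaving out either wild-type replicate also ended the call on the right arm of III, while its difference stayed at -0.11. Wild-type libraries do not enter this difference, and only the shared spread behind the test changed.

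On the right arm of V, LEM-2 enrichment was lower in cec-4 than in met-2 set-25 by 0.28. On this arm the fall in cec-4 was 1.75 times that in met-2 set-25. If 1 such factor held everywhere, the autosomal centres would differ by -0.20, and they differed by -0.026 (SE 0.04). This argues against 1 general factor as the whole cause. The factor was taken from this arm, which was picked for its difference, so a smaller general difference between the mutants stays open. A single library alone is argued against by the difference without each mutant pair in turn, the smallest being 0.20 without cec-4 replicate 2, and the inputs by their own difference on this arm, -0.0404 as cec-4 minus met-2 set-25, which is opposite in sign to what they would need. The spread stays open, since the cec-4 libraries had 0.04 and -0.10 on this arm and with the region's own variance the adjusted p was 0.238. A difference between the genotypes may remain as a hypothesis, and the strains may also have differed in the mix of embryo stages, which was not tested.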

How the results depend on the processing

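The fits without the last window of I, with crossed wild-type numbers, with each region's own variance and of the 6 inputs alone, and the DESeq2 count without LEM-2 met-2 set-25 replicate 2, were chosen only after the data were seen. No called region and no named called window changed sign. Of the called windows of wild-type against input 1 was called with the opposite sign in the DESeq2 Wald test. Under TMM factors the left arm of V in cec-4 (0.01 to -0.12), the left arm of X in cec-4 (0.03 to -0.09) and the first 4 Mb of X in met-2 set-25 (0.00 to -0.09) took the opposite sign and were called. Against input, the number of called windows ranged over the left-out libraries from 454 to 481 in wild-type, 332 to 414 in met-2 set-25 and 370 to 430 in cec-4, and against wild-type from 360 to 428 in met-2 set-25 and 373 to 433 in cec-4. The inputs had 0 called windows in each edgeR fit and in DESeq2 with all libraries, with 0 at an unadjusted p under 0.05 in edgeR with all libraries, 18 in met-2 set-25 and 86 in cec-4 in a fit of the inputs alone, and 1 and 20 called by DESeq2 on the inputs alone. Between the mutants the count ranged from 0 to 141 (the 0 by edgeR without LEM-2 met-2 set-25 replicate 2, with 81 at an unadjusted p under 0.05 and 34 by DESeq2, and the 141 without LEM-2 cec-4 replicate 1), was 64 in the DESeq2 Wald test against 41 in edgeR, and the cause was not tested. Of the 23 overlapping region lists (18 regions and 5 pooled lists), 20 in met-2 set-25 and 18 in cec-4 were called, of which 16 and 14 were among the 18 regions. Over the left-out replicates the lists called ranged from 19 to 20 in met-2 set-25, 17 to 19 in cec-4 and 1 to 5 between the mutants, and TMM factors gave 22, 23 and 4. Between the mutants 4 lists were called, 2 after centring on the median autosomal window and 0 with each region's own variance (4 at an unadjusted p under 0.05), where fewer degrees of freedom stand behind each test. Arm minus centre changed by -0.55 to -0.43 in met-2 set-25 and by -0.61 to -0.49 in cec-4 over the left-out replicates, and by -0.59 in met-2 set-25 with medians over windows, and the cause of that shift was not tested. The correlation of the mutants' changes ranged from 0.92 to 0.97 over the left-out replicates. With wild-type library 1 for met-2 set-25 and library 2 for cec-4 it was 0.90. The reverse assignment used equally few libraries and gave a higher r, and the cause of the lower value was not tested. Where a fit left a group with 1 library, that library was assumed to vary like those of the other groups.

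With the replicate block 471 windows differed from input in wild-type, 382 in met-2 set-25 and 409 in cec-4, 401 and 399 changed against wild-type in met-2 set-25 and cec-4, 42 differed between the mutants and 0 between inputs, and the correlation was 0.95. The block gave 20, 17 and 3 lists, and it ended the call on the right arm of III in cec-4 and between the mutants and no other region call. With the wild-type numbers crossed, 410 and 409 windows and 21 and 20 lists changed in met-2 set-25 and cec-4. The block within each genotype gave 417 changed windows in met-2 set-25 and 412 in cec-4, and 48 between the mutants. Of the single list values under the alternatives, 1199 were the same, 16 gained a call with the same sign and 33 lost one. A further 40 uncalled values took the opposite sign, among them those named above as called under TMM factors. Of the single values of named windows under the alternatives, 767 were the same and 32 lost a call, all of these between the mutants. The filter removed no window, and corrections for GC content were not run. Counting error was at most 0.716% of the median window if each count was an independent fragment.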

Other observations

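The tests of explanations and the stretches in this part were all chosen only after the results were seen. An interior stretch of IV, 4.8 to 7 Mb, was the longest run of enriched windows in an autosomal centre of cec-4. Over its 11 windows the log2 ratio was -0.04 ± 0.05 in wild-type, 0.19 ± 0.00 in met-2 set-25 and 0.32 ± 0.06 in cec-4 (SD, n = 2). In wild-type 1 of these windows was enriched and in met-2 set-25 8, while in cec-4 the 11 follow from how the stretch was chosen. The cec-4 values here, and the wild-type values of the stretches below, are favoured by the choice. The longest enriched run of wild-type, the 24 windows of V from 16.2 Mb to the right end, had 0.57 ± 0.02 in wild-type, 0.23 ± 0.03 in met-2 set-25 and -0.02 ± 0.09 in cec-4 (SD, n = 2). The left tip of X, 0 to 0.8 Mb, had 4 windows enriched in all 3 genotypes, at 0.54 ± 0.00, 0.37 ± 0.00 and 0.30 ± 0.03 (SD, n = 2).

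Windows called enriched lay in fewer runs in wild-type than in the mutants. There were 27 runs of enriched windows in wild-type with a median of 3 windows, 65 in met-2 set-25 with a median of 2 and 66 in cec-4 with a median of 1, and the longest held 24, 21 and 22 windows. Depleted windows formed 24, 63 and 72 runs, and the longest held 38 windows in wild-type and 15 in either mutant. Runs were counted from calls under library totals only. Autosomal arm windows without a call numbered 15 in wild-type, 53 in met-2 set-25 and 36 in cec-4. A flatter profile alone can thus break runs, and these counts do not by themselves show a more broken pattern.

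The smaller height of arms above centres in both mutants was set against technical explanations. A less specific immunoprecipitation, which mixes the wild-type profile with input-like background, would bring all 18 regions towards input by 1 factor per mutant. The SD of the regions around the best factor was 3.90 times a standard error in met-2 set-25 and 4.45 times in cec-4. That standard error came from the spread between replicates, for the mutant mean minus the scaled wild-type mean of 2 libraries each. These values argue against such background as the whole cause. The inputs are argued against as well, since LEM-2 counts alone gave 98.8% of the change in met-2 set-25 and 106% in cec-4. A partial loss of specificity stays open, as does a different mix of embryo stages between strains, which was not tested. A difference between the genotypes themselves stays open as a hypothesis that these tests do not decide.

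The change in the outermost windows of the autosomes was compared with that in the rest of the outer part of their arm. The mean change of the 10 end windows was -0.11 in met-2 set-25 and -0.036 in cec-4, against -0.27 and -0.34 for the rest, so the end lay above the rest by 0.16 and 0.30 on average, at 8 of 10 ends in each. At 4 ends in met-2 set-25 and 5 in cec-4 the window lay above its wild-type level, the highest being the left end of II (0.20 and 0.36). These counts and changes depended on the scaling, and under TMM factors or DESeq2 size factors 2 ends in met-2 set-25 and 4 in cec-4 lay above wild-type. The mean change of the ends was then -0.21 in met-2 set-25 and -0.16 in cec-4 under TMM factors, and -0.25 and -0.17 under DESeq2 size factors. The highest end had 0.11 and 0.23 under TMM factors and 0.066 and 0.23 under DESeq2 size factors. The sign-flip permutation test gave p = 0.0488 and 0.00781. It takes the ends as its units, which all come from the same libraries, so its p measures the spread between ends and not between libraries. Leaving out any 1 of 8 of the 10 ends took p past 0.05 in met-2 set-25, up to 0.0977 without the left end of II, while in cec-4 p stayed between 0.00781 and 0.0156 without any 1 end. A p under 0.05 in both mutants was at first set down as evidence that ends keep more of their wild-type level, and this was met, but after the result was seen it was held too weak for met-2 set-25, and the question stays open. The windows at right ends are shorter than the others.

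Whether arms with a higher wild-type level changed more was tested across the 10 autosomal arms, with the level from one wild-type library and the change against the other. The correlations r lay between -0.51 and -0.17 over the 4 combinations of mutant and library, with permutation p between 0.131 and 0.642 and adjusted p between 0.509 and 0.642. Leaving out the 2 arms farthest from the median level gave r between -0.51 and 0.23. A p of 0.05 or more was at first set down as evidence against this relation, but 10 arms are too few for that, and the question stays open.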
